A study of Homo sapiens with 9 samples.

How the data were processed

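Total RNA of T47D cells had been labelled with biotin and hybridised to Affymetrix expression arrays, 1 array per sample and 9 in all. The deposited values were log2 expression values per probe set, given with 2 decimals. The submitters' processing notes name RMA, which corrects the background of the probes, quantile normalizes the arrays and summarises the probes of each probe set. The version of the software is not given in the sources used here. Array medians lay between 6.43 and 6.49 and no value was missing, so no further scaling was applied before the tests. The labels name a larger array than the one whose probe sets the table held, so genes carried by the larger array alone were not analysed here.

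The table held 22215 probe sets. Of these, 19064 carried exactly 1 gene symbol, 1043 carried several and 2108 carried none, and control probe sets numbered 0. Symbols were checked by Entrez Gene identifier against the RefSeq annotation of the GRCh38.p14 assembly, where 19052 probe sets were matched and 0 symbols needed an update. The unit of test was the gene. Where a gene had several probe sets, as 4310 genes did, the probe set with the highest mean over the 9 arrays stood for it, which gave 11963 genes. No filter on dim genes was applied. The number of columns that could not be assigned to a group was 0.

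Arrays were grouped by the sample titles into parental, resistant and ex-resistant cells, with 3 arrays in each group. A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation without a trend. The fit had 6 residual degrees of freedom and a prior of 5.53, and the median standard error of a difference was 0.0910 on the log2 scale. The 3 differences between groups were tested with limma's moderated test, two-sided, and a moderated F-test compared all 3 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 11963 genes, and counts of genes that also differed at least 2-fold were kept beside these. The number of arrays limits the precision of these values. The labels do not say whether arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

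The sample titles number the repeats, and whether equal numbers mark pairs was checked on the values. After group means were removed, parental and resistant arrays with the same number correlated over genes with r between 0.17 and 0.26, and those with other numbers with r between -0.25 and 0.02. For parental and ex-resistant arrays the same-number values were 0.03 to 0.14, and for resistant and ex-resistant arrays -0.06 to 0.09. The numbers thus paired parental with resistant arrays only, and a fit with the repeat number as a block was run as an alternative. That fit called 2448 genes in resistant against parental, 4979 in ex-resistant against resistant and 5534 in ex-resistant against parental cells.

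Reversal was counted among the genes called in resistant against parental cells. Counted were those called in the opposite direction in ex-resistant against resistant cells, those of them not called against parental cells, and those called in the same direction in ex-resistant against parental cells. Because these comparisons share arrays, the covariance between them was set beside that of 100 simulations with equal group means.

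The question, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. The 28 lists covered the CDK4/6-RB axis, E2F targets of G1/S and DNA replication, G2/M and mitosis, TGF-beta ligands, receptors and SMADs, TGF-beta target genes, oestrogen response, luminal identity, mesenchymal genes, basal, fibroblast and leukocyte markers, interferon-stimulated genes, antigen presentation, MAPK output, receptor tyrosine kinases, lysosome and autophagy, cholesterol synthesis, fatty acid synthesis, the ATF4 and unfolded protein response, hypoxia and glycolysis, oxidative phosphorylation, p53 targets, senescence-associated secretory genes, exosome biogenesis, microRNA processing, the 14q32 imprinted locus, drug transport and metabolism, and histones. They held 671 distinct measured genes, and 28 pairs of lists shared at most 7 genes. Lists with at least 5 measured genes, 27 in all, were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction, and neither compares the list with other genes.

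Named genes were a panel of cell-cycle, TGF-beta and oestrogen receptor genes, whatever their result, the 8 largest rises and the 8 largest falls of each comparison among called genes whose arrays did not overlap between the groups, and up to 4 members of each list with the smallest p among the called ones. For the reversal, the 6 largest changes in each direction were taken. The text names the panel and a part of the others.

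The fit was tested on simulated data with 11963 genes of which 200 differed in the first comparison. It recovered 96% of genes that differed by 0.5 on the log2 scale and 100% of those that differed by 1, with 9 false calls, 4.35% of all calls. The simulated noise was normal and independent between genes, so this check covers neither correlated genes nor probe sets of a gene that disagree. Alternatives fixed in advance were the replicate block, a fit to the 6 arrays compared for counts and named genes, quantile normalization or median centring of the arrays, filters on dim genes, other ways of representing a gene by its probe sets, another moderation, array weights, a threshold of 0.01 and leaving out each array in turn. Cyclic loess between arrays, a count that required both of a gene's 2 brightest probe sets, the fit to 6 arrays for the lists and the covariances without a shared array were added after the data had been seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.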

Results

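Transcript levels were measured in T47D, an oestrogen receptor-positive luminal breast cancer line, on 9 arrays. The parental group had 3 arrays. The resistant group had 3 arrays of cells grown in 100 nM palbociclib, an inhibitor of the cell-cycle kinases CDK4 and CDK6, to which they had become resistant. The ex-resistant group had 3 arrays of cells that had first become resistant and had then grown without the drug for at least 7 weeks. The study's title concerns the suppression of the TGF-beta pathway by microRNAs in resistance that can be transmitted and reversed, and the 3 groups address which changes go with resistance and which remain after the drug is gone. Over the 22215 probe sets, arrays of the same group correlated with r of 0.995 to 0.998, and parental with resistant arrays with r of 0.990 to 0.992. The ex-resistant arrays stood apart, with r of 0.974 to 0.981 to the parental and 0.976 to 0.983 to the resistant arrays. These values are taken across probe sets, which are not independent replicates. The first principal component, 59.3% of the variance, set the ex-resistant arrays apart from the other 6.

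Resistant cells were compared with parental cells to ask which transcripts go with resistance and growth in the drug. CCND1, which encodes the CDK4/6 partner cyclin D1, rose by 1.24 ± 0.20 on the log2 scale (SE, n = 3 arrays per group, adjusted p = 0.00111), from 9.55 ± 0.24 to 10.79 ± 0.29 (SD). CDKN1A, the gene of the CDK inhibitor p21, fell by 1.11 ± 0.08 (adjusted p = 3.11e-06), and CDK6 rose by 0.45 ± 0.11 from a low level of 4.02. The TGF-beta co-receptor gene TGFBR3 fell by 2.02 ± 0.13 and the oestrogen-induced peptide gene TFF1 by 2.37 ± 0.26. TWIST1, a transcription factor of epithelial-mesenchymal transition, rose by 3.66 ± 0.13 from 4.70, and CALCR, the calcitonin receptor gene, fell by 5.25 ± 0.18 to 4.31. Both of these levels lie close to the floor of the arrays.

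Genes of the cell cycle were lower in part. Of 27 measured genes of the CDK4/6-RB axis, 2 rose, 7 fell and 18 did not pass (2 and 8 adjusted over the list alone), and the list did not pass its test (adjusted p = 0.128). RB1, the retinoblastoma gene that restrains E2F, fell by 0.52 ± 0.12. It lies on chromosome 13, where 59 of 113 genes with a mean over 6 fell, and its other, dim probe set did not pass (-0.07). CDK2 fell by 0.28 ± 0.07 (-0.23, adjusted p = 0.107, with the mean of its probe sets) and CCNE2, a cyclin E gene, by 0.47 ± 0.11, while CDK4 (-0.23), CCND3 (0.03), CCNE1 (-0.05), E2F1 (0.04), CDKN2B (-0.09) and MKI67 (-0.39 ± 0.13, adjusted p = 0.0585) did not pass. CDK4 passed without parental replicate 3 (-0.36, adjusted p = 0.0110). MKI67 passed under 7 alternatives that kept the 6 arrays compared (-0.56 to -0.39, adjusted p = 0.0232 to 0.0495), and its 3 other probe sets were called lower. It also passed without parental replicate 3 (-0.49, adjusted p = 0.0319) or ex-resistant replicate 3 (-0.39, adjusted p = 0.0205). Among 43 E2F targets of G1/S and DNA replication, 0 rose and 11 fell, with the same counts adjusted over the list alone. These included SLBP, which binds histone mRNA (-0.77 ± 0.09), and the nucleotide synthesis genes TYMS (-0.72 ± 0.09) and RRM2 (-0.52 ± 0.08; -0.24, adjusted p = 0.171, by its probe set of largest interquartile range). The E2F list passed as lower (median -0.11, adjusted p = 0.000107, adjusted p = 0.617 with an estimated correlation and 0.0868 by fry). The 39 genes of G2/M and mitosis passed as lower too (adjusted p = 0.0162, adjusted p = 0.628 with an estimated correlation and 0.162 by fry), although 33 of them did not pass singly. CCNA2 (-0.48 ± 0.10) and CCNB1 (-0.28 ± 0.07) were among 5 that fell, and TTK (0.36 ± 0.08) was the 1 that rose. The counts adjusted over the list alone were also 5 and 1. Of 10 histone genes, 1 rose, H2AC6 (0.73 ± 0.19), and 9 did not pass (list adjusted p = 0.728).

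Interferon-stimulated genes, which encode antiviral effectors, fell as a group. Of 35 measured, 25 fell, 1 rose and 9 did not pass (30 and 1 adjusted over the list alone). IFIT5 fell by 1.86 ± 0.14, MX1 by 1.84 ± 0.16 and OAS3 by 1.28 ± 0.12, and HERC5, a ligase for the ubiquitin-like ISG15, was the 1 that rose (1.22 ± 0.12). The median was -0.63 and the list passed (adjusted p = 1.52e-15, adjusted p = 0.169 with an estimated correlation). Of 29 senescence-associated secretory genes, 10 fell and 0 rose (12 and 0 adjusted over the list alone), among them the protease inhibitor gene SERPINE2 (-2.69 ± 0.12) and the chemokine genes CXCL2 (-0.99 ± 0.10) and CCL2 (-1.15 ± 0.14). That list passed with adjusted p = 0.000107, and with adjusted p = 0.0691 with an estimated correlation. Of 18 antigen presentation genes 6 fell, such as the immunoproteasome gene PSMB10 (-0.41 ± 0.07), 1 rose and the list did not pass (adjusted p = 0.128).

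Of 18 genes of cholesterol synthesis and SREBP2 control, 9 rose and 1 fell (10 and 1 adjusted over the list alone), with the sterol enzymes SC5D (0.75 ± 0.09), TM7SF2 (0.64 ± 0.08) and SQLE (0.57 ± 0.08; 0.37, adjusted p = 0.179, by its probe set of largest interquartile range) among the risen. The list median was 0.32 (adjusted p = 0.00407, adjusted p = 0.169 with an estimated correlation). Of 15 fatty acid synthesis genes, 5 rose and 0 fell, with equal counts adjusted over the list alone, including the elongase ELOVL6 (0.70 ± 0.09) and ACSL1 (0.48 ± 0.09). The fatty acid list passed with adjusted p = 0.0482, against adjusted p = 0.0505 with the replicate block and adjusted p = 0.169 with an estimated correlation. The amino acid response genes went both ways. SLC7A5, an amino acid transporter gene, fell by 0.79 ± 0.07 and ASNS, asparagine synthetase, rose by 0.57 ± 0.07, and the list did not pass (5 of 30 higher, 6 lower, adjusted p = 0.0698). The vasodilator gene ADM fell by 2.95 ± 0.12 and the collagen hydroxylase gene P4HA2 by 0.67 ± 0.07 in the hypoxia and glycolysis list, of which 5 of 35 rose and 8 fell (adjusted p = 0.128). For oxidative phosphorylation, 2 of 38 rose, such as NDUFB3 (0.33 ± 0.07), and 2 fell (adjusted p = 0.636).

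The oestrogen receptor gene ESR1 (-0.03 ± 0.07), PGR (0.22 ± 0.12) and GREB1 (-0.01 ± 0.10) did not pass, although PGR did without parental replicate 3 (0.36, adjusted p = 0.0487). Other oestrogen-responsive genes went both ways. Of 35 on the list 13 fell and 6 rose, over all genes and adjusted over the list alone. TFF3 fell by 1.63 ± 0.09 and the scaffold gene PDZK1 by 1.16 ± 0.10, and the elongase gene ELOVL2 rose by 1.96 ± 0.12 (0.43, adjusted p = 0.0634, by its probe set of largest interquartile range). The list passed as lower (adjusted p = 0.0482), against adjusted p = 0.0806 with the replicate block and adjusted p = 0.169 with an estimated correlation. Of 17 basal epithelial markers 5 fell and 1 rose (the same adjusted over the list alone), including ACTA2 (-0.94 ± 0.11), TRIM29 (-0.92 ± 0.12) and EGFR (-0.66 ± 0.10), and the list passed as lower (adjusted p = 0.0463, adjusted p = 0.169 with an estimated correlation). With the mean of all probe sets, TRIM29 (-0.29, adjusted p = 0.0514) and EGFR (-0.13, adjusted p = 0.224) did not pass. The oestrogen, basal and fatty acid lists did not pass in the fit to the 6 parental and resistant arrays, which was extended to the lists after the data had been seen (adjusted p = 0.0584, 0.0565 and 0.0584). Of 30 luminal genes 7 rose, among them KRT7 (0.81 ± 0.10) and ERBB2 (0.54 ± 0.07), and 2 fell (adjusted p = 0.128).

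TGF-beta pathway genes did not pass as a group. Of 32 ligands, receptors and SMADs, 4 rose and 5 fell, with equal counts adjusted over the list alone (adjusted p = 0.965). SMAD4, the common mediator of TGF-beta and BMP signals, fell by 0.78 ± 0.08, the latent TGF-beta binding gene LTBP1 by 0.67 ± 0.09 and the pseudoreceptor gene BAMBI by 0.75 ± 0.13. TGFBR1 (-0.15), TGFBR2 (0.01, at a level of 4.23 close to the floor), SMAD2 (-0.18), SMAD3 (0.30) and SMAD7 (0.06) did not pass, although SMAD3 did without ex-resistant replicate 1 (0.30, adjusted p = 0.0460). Of 33 TGF-beta target genes 8 fell and 4 rose (10 and 4 adjusted over the list alone), with the BMP-responsive ID3 (-1.29 ± 0.12) and ID1 (-1.05 ± 0.15) down and the actin-binding TAGLN up (0.67 ± 0.09), and the list did not pass (adjusted p = 0.0600, adjusted p = 0.00548 by fry).

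The other lists did not pass, and counts adjusted over the list alone differed by at most 3 genes from those given for lists that did not pass. Mesenchymal genes had 2 of 29 higher, TWIST1 and VIM (0.68 ± 0.13), and 3 lower, such as S100A4 (-0.53 ± 0.12), with adjusted p = 0.996. Fibroblast markers had 1 of 16 lower, S100A4, and leukocyte markers 1 of 18 higher, ITGB2 (0.45 ± 0.09), each with adjusted p = 0.996. MAPK output had 3 of 22 higher and 5 lower, including PHLDA1 (-1.13 ± 0.08) and EPHA4 (-1.64 ± 0.12), with adjusted p = 0.448. Receptor tyrosine kinases had 6 of 30 higher and 5 lower, including ERBB4 (-1.12 ± 0.09), with adjusted p = 0.996, and FGFR1 did not pass (0.03). Lysosome genes had 6 of 34 higher and 6 lower, among them GPNMB (-1.12 ± 0.17), with adjusted p = 0.996. For p53 targets, 4 of 23 rose, such as SESN1 (0.65 ± 0.08), and 5 fell, such as FAS (-0.97 ± 0.07), with adjusted p = 0.128. Exosome genes had 5 of 27 higher, with CD9 at 0.72 ± 0.10, and 4 lower, with CD63 at -0.39 ± 0.07 (adjusted p = 0.636). In microRNA processing 1 of 11 rose, the nuclease gene DROSHA (0.65 ± 0.08), and 10 did not pass (adjusted p = 0.693). Of 4 measured genes of the 14q32 imprinted locus, too few for a test, 0 passed, DLK1 with -0.15. Drug transport and metabolism had 3 of 26 higher, with CYP1A1 at 0.90 ± 0.08, and 4 lower, with ALDH1A3 at -1.46 ± 0.18 (adjusted p = 0.965).

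In all, 2319 of 11963 genes were called, 1209 higher and 1110 lower, and 218 of them differed at least 2-fold (121 and 97). The arrays of the 2 groups did not overlap in 34.99% of genes, where chance gives 10%. The call of CDK6 was lost without resistant replicate 1 (0.38, adjusted p = 0.0627), that of CDK2 without parental replicate 1, parental replicate 2 or resistant replicate 3 (-0.27 to -0.25, adjusted p = 0.0554 to 0.0721), and that of H2AC6 without parental replicate 1 or 2 or resistant replicate 1 or 3 (0.57 to 0.75, adjusted p = 0.0509 to 0.0913). Of the lists past the threshold in any comparison, with 8 in this one, 0 held with an estimated correlation, where the lowest adjusted p was 0.0691.

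**Figure D1:**
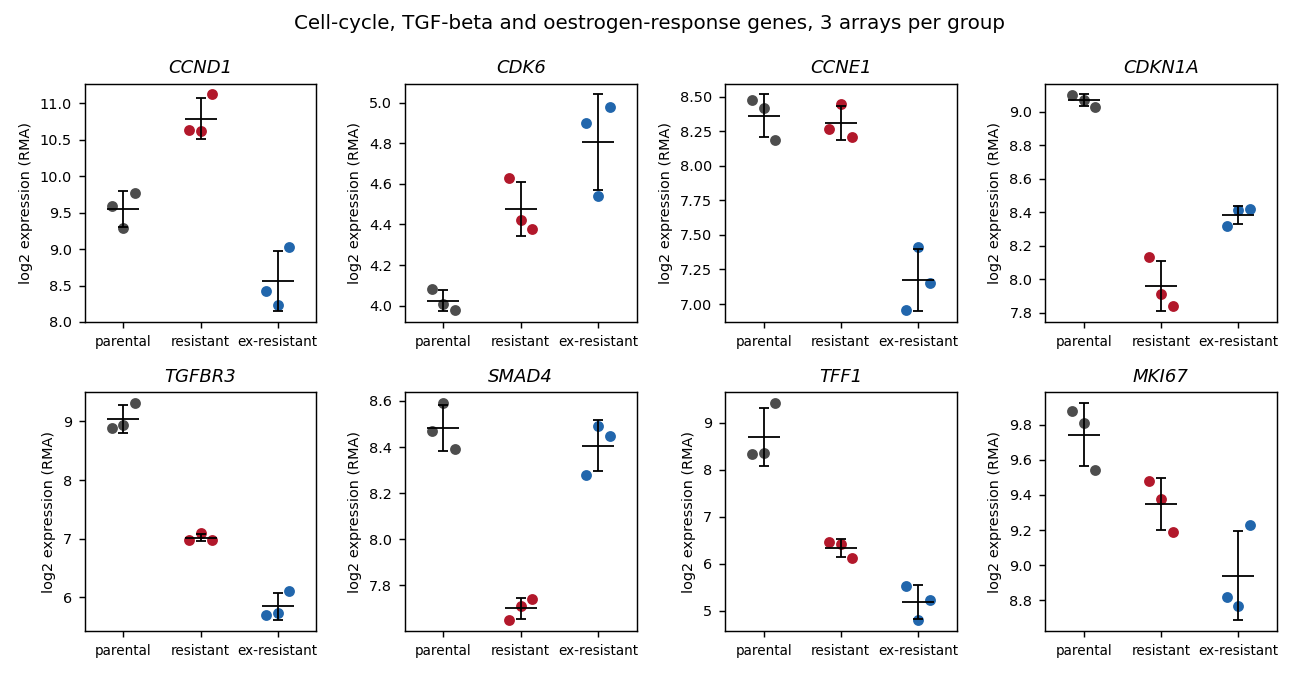
Log2 expression (RMA) of 8 genes in parental, resistant and ex-resistant cells, with 1 point per array, the mean as a horizontal line and the SD as error bars (3 arrays per group). CCND1 went from 9.55 in parental to 10.79 in resistant and 8.56 in ex-resistant cells, and SMAD4 from 8.48 to 7.70 and 8.41.

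Ex-resistant cells were compared with resistant cells to ask what changed during growth without the drug. CCND1 fell by 2.23 ± 0.20 (SE, n = 3 arrays per group, adjusted p = 7.72e-06), to 8.56 ± 0.42 (SD), and CCNE1, a cyclin E gene, fell by 1.14 ± 0.12 (adjusted p = 2.46e-05). The interferon-induced gene IFI27 fell by 5.98 ± 0.27, to 4.62 close to the floor, and LEF1, a transcription factor of Wnt signalling, fell by 4.16 ± 0.18. The heparan sulfate-editing gene SULF1 rose by 3.52 ± 0.17, and the Wnt inhibitor gene DKK1 rose by 3.27 ± 0.18. SMAD4 rose by 0.71 ± 0.08 and PSAT1, an enzyme of serine synthesis, by 2.89 ± 0.13.

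These values carry the difference of the ex-resistant arrays from the other 6. Over 2408 genes with 2 bright probe sets, the log2 differences of the 2 correlated with r of 0.851 (95% interval 0.821 to 0.875) in resistant against parental cells. It was 0.421 (0.371 to 0.470) here and 0.468 (0.417 to 0.518) in ex-resistant against parental cells. These values are across genes, which are not independent replicates. Where both probe sets were called, they moved in opposite directions in 2 of 308, 248 of 805 and 234 of 861 genes. Among the panel, CCNE2, RB1, ESR1, FGFR1, SMAD2 and SMAD3 had probe sets called in opposite directions in ex-resistant cells.

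**Figure D2:**
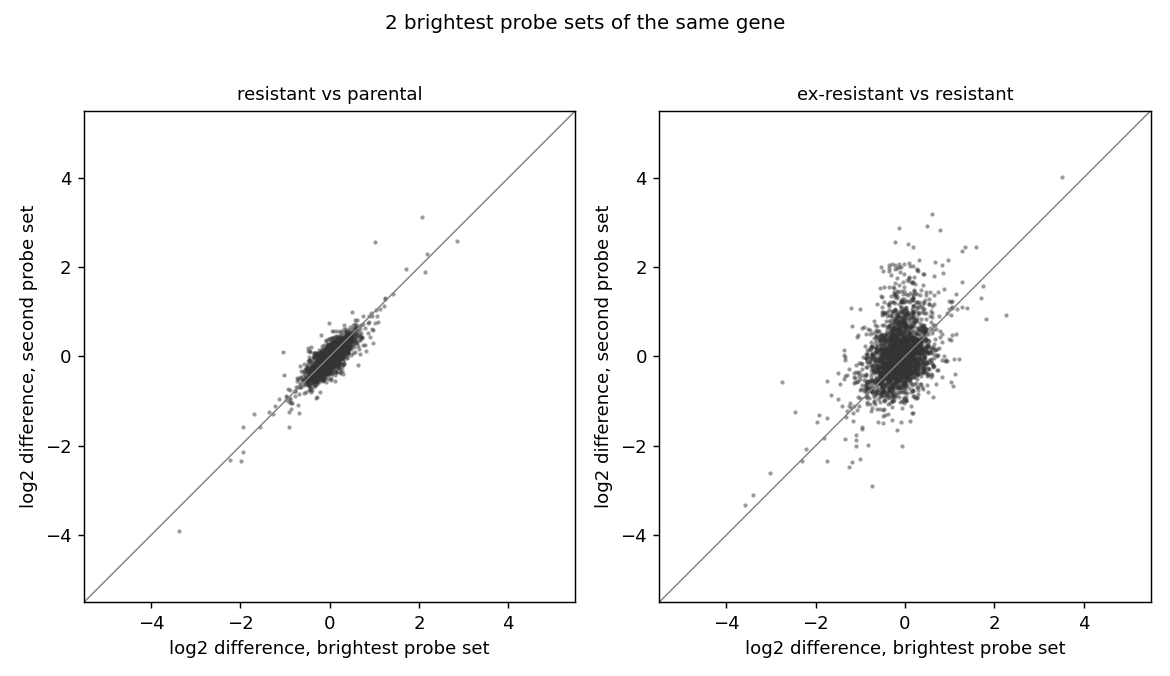
Log2 difference of the second brightest against that of the brightest probe set of 2408 genes, with 1 point per gene and the diagonal of equal change, in resistant vs parental and ex-resistant vs resistant cells. Points follow the diagonal with r of 0.851 in resistant vs parental and 0.421 in ex-resistant vs resistant cells.

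Of 39 genes of G2/M and mitosis, 25 fell and 2 rose (29 and 2 adjusted over the list alone), including the kinetochore genes CENPF (-0.74 ± 0.07) and CENPE (-0.75 ± 0.10) and the kinesin KIF23 (-0.80 ± 0.10), and the list passed (median -0.44, adjusted p = 2.94e-06, adjusted p = 0.672 with an estimated correlation). Of the 12 members with 2 bright probe sets, 4 fell by both and 2 moved in opposite directions. MKI67, a marker of cycling cells, was at -0.41 ± 0.13 (adjusted p = 0.0274), a call lost without resistant replicate 1 or 2 or ex-resistant replicate 1 or 2 (-0.39 to -0.33, adjusted p = 0.0723 to 0.105). E2F targets had 18 of 43 lower, such as the replication gene GINS1 (-0.87 ± 0.09), and 7 higher (19 and 8 adjusted over the list alone), and did not pass (adjusted p = 0.372). Of the 13 E2F targets with 2 bright probe sets, 1 fell by both, 1 rose by both and 5 moved in opposite directions. On the CDK4/6-RB axis 9 of 27 fell and 8 rose (adjusted p = 0.985, 9 and 9 adjusted over the list alone). CDK4 rose by 0.52 ± 0.11, CDK2 by 0.49 ± 0.07 and CDKN1A by 0.42 ± 0.08, CCND3 fell by 0.61 ± 0.11, and E2F1 (-0.17) and CDKN2B (0.11) did not pass. CDK6, at levels of 4.48 and 4.81 close to the floor, rose by 0.33 ± 0.11, a call lost without resistant replicate 2 or 3 or ex-resistant replicate 1 or 3 (0.24 to 0.30, adjusted p = 0.101 to 0.118) and under 5 alternatives that kept the 6 arrays compared (0.24 to 0.33, adjusted p = 0.0555 to 0.101). CCNE2 was at -0.36 ± 0.11 by its brightest probe set, lost without resistant replicate 1 or 2 or ex-resistant replicate 1 (-0.32 to -0.27, adjusted p = 0.0694 to 0.0889), and at 2.04 by its other probe set. RB1, on chromosome 13, was at -0.48 ± 0.12 by the brightest and at 0.92 by the other. Histone genes had 5 of 10 higher and 1 lower, with H4C8 at 1.78 ± 0.12, and did not pass (adjusted p = 0.0646; 0.0279 in the fit to 6 arrays).

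Interferon-stimulated genes fell again. Of 35, 26 fell and 1 rose (29 and 2 adjusted over the list alone), with IFIT1 at -2.94 ± 0.20 and ISG15 at -2.43 ± 0.22 and a median of -0.69. The list passed (adjusted p = 6.28e-08, adjusted p = 0.512 with an estimated correlation), and 1 member had 2 bright probe sets. Antigen presentation genes had 4 of 18 lower, such as the peptide transporter TAP1 (-0.76 ± 0.10), and 2 higher (adjusted p = 0.997). Secretory genes of senescence had 7 of 29 lower, such as TIMP1 (-2.88 ± 0.20), and 6 higher (adjusted p = 0.985).

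Of 30 genes of the ATF4 and unfolded protein response, 15 rose and 6 fell (15 and 7 adjusted over the list alone), and the list passed (median 0.18, adjusted p = 0.0183, adjusted p = 0.487 with an estimated correlation). The risen included PSAT1, PHGDH, which opens the serine pathway (0.75 ± 0.07), and the paired amino acid transporter genes SLC7A5 (1.14 ± 0.07) and SLC3A2 (1.29 ± 0.08). Both probe sets were called alike in 0 of the 6 members with 2 bright probe sets. Of 35 oestrogen-responsive genes 18 fell and 7 rose, with equal counts adjusted over the list alone, with TFF3 at -2.67 ± 0.09, TFF1 at -1.16 ± 0.26, the growth factor-binding IGFBP5 at -1.75 ± 0.11 and the receptor gene NPY1R at -1.74 ± 0.15. That list passed (median -0.26, adjusted p = 0.0313, adjusted p = 0.456 with an estimated correlation), and of 14 members with 2 bright probe sets 7 fell by both and 1 moved in opposite directions. ESR1 was at -0.40 ± 0.07 by its brightest probe set and at 0.85 by another, and PGR (0.13) and GREB1 (-0.20) did not pass. GREB1 passed with the mean of its probe sets (-0.50, adjusted p = 0.0237), with array weights (-0.26, adjusted p = 0.0318) and without resistant replicate 3 (-0.31, adjusted p = 0.0153).

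Within the TGF-beta pathway, TGFBR3 fell by 1.17 ± 0.13 and the BMP receptor gene BMPR2 by 1.36 ± 0.15, and TGFBR1 rose by 0.84 ± 0.12. SMAD3 was at -0.98 ± 0.12 and SMAD2 at -0.65 ± 0.12 by the brightest probe set, and SMAD2 at 0.54 by another, while TGFBR2 (0.01) and SMAD7 (-0.23) did not pass. SMAD7 passed with the replicate block (-0.23, adjusted p = 0.0277) and under 2 other alternatives, for 3 in all (-0.26 to -0.23, adjusted p = 0.0277 to 0.0498). Of 32 ligands, receptors and SMADs 8 rose and 7 fell, with equal counts adjusted over the list alone (adjusted p = 0.997). Among 33 TGF-beta targets 10 rose and 5 fell, again equal over the list alone, with ID1 up by 2.43 ± 0.15 and ID3 up by 1.77 ± 0.12 and PMEPA1, a feedback inhibitor of TGF-beta signalling, down by a log2 difference of -1.75 ± 0.15, and the list did not pass (adjusted p = 0.372).

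The remaining lists did not pass, with counts adjusted over the list alone at most 3 genes away for lists that did not pass. Luminal genes had 7 of 30 higher, such as CLDN3 (1.34 ± 0.09) and KRT8 (0.78 ± 0.09), and 9 lower, such as MUC1 (-0.78 ± 0.07), with adjusted p = 0.985. Mesenchymal genes had 6 of 29 higher, with S100A4 at 0.92 ± 0.12, and 3 lower (adjusted p = 0.539). Basal markers had 5 of 17 higher, with ACTA2 at 0.94 ± 0.11, and 4 lower (adjusted p = 0.634). Fibroblast markers had 3 of 16 higher and 2 lower (adjusted p = 0.580), and leukocyte markers had 2 of 18 higher, with LCP1 at 0.57 ± 0.07, and 1 lower (adjusted p = 0.570). Cholesterol synthesis had 4 of 18 higher and 8 lower, with INSIG1 at -1.33 ± 0.14 (adjusted p = 0.570). Other probe sets of INSIG1 were at -0.45 and -0.15. Of the 9 cholesterol genes with 2 bright probe sets, 0 rose by both, 1 fell by both and 4 moved in opposite directions. Fatty acid synthesis had 0 higher and 7 of 15 lower, with PNPLA3 at -1.19 ± 0.10 (adjusted p = 0.114). Lysosome genes had 9 of 34 higher and 11 lower, with the autophagy gene WIPI1 at -1.93 ± 0.08 (adjusted p = 0.634). Hypoxia and glycolysis had 9 of 35 higher and 12 lower, with PFKFB3 at -1.20 ± 0.10 and hexokinase gene HK2 at -0.93 ± 0.11 (adjusted p = 0.760). Oxidative phosphorylation had 8 of 38 higher, with UQCRC1 at 0.86 ± 0.09, and 3 lower (adjusted p = 0.372). The p53 targets had 6 of 23 higher, with TP53I3 at 1.28 ± 0.10, and 6 lower, with PLK2 at -1.53 ± 0.14 (adjusted p = 0.985). MAPK output had 4 of 22 higher and 7 lower, with the phosphatase DUSP4 at -1.19 ± 0.12 (adjusted p = 0.985). Receptor tyrosine kinases had 0 of 30 higher and 6 lower, with FGFR3 at -1.06 ± 0.09 (adjusted p = 0.609). FGFR1 did not pass (-0.03) by its brightest probe set and was at 0.76 by another. Exosome genes had 5 of 27 higher and 10 lower, with CD81 at -1.16 ± 0.08 (adjusted p = 0.570). MicroRNA processing had 2 of 11 higher and 2 lower, with TNRC6B at -0.89 ± 0.09 (adjusted p = 0.985). Drug metabolism had 5 of 26 higher and 5 lower, with CYP1A1 at -0.88 ± 0.08 and TIPARP at -0.81 ± 0.07 (adjusted p = 0.985). The imprinted transcript MEG3 of 14q32 fell by 0.39 ± 0.08.

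In total 4812 genes were called, 2002 higher and 2810 lower, with 401 that differed at least 2-fold (157 and 244). The arrays of the 2 groups did not overlap in 50.7% of genes, against 10% by chance. Among the 2408 genes with 2 bright probe sets, the brightest called 1264. When both had to be called alike, an alternative added after the data had been seen, 557 of the 2408 were called and 44 of them differed at least 2-fold. With an estimated correlation, the lowest adjusted p of the 4 passing lists and all others was 0.456.

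Ex-resistant cells were compared with parental cells to ask what differed once the drug was gone. TWIST1 was higher by 4.10 ± 0.13 (SE, n = 3 arrays per group, adjusted p = 1.85e-09), and the interleukin-1 receptor gene IL1R1 by 3.46 ± 0.13, the KIT ligand gene KITLG by 3.10 ± 0.10 and the syndecan gene SDC2 by 2.96 ± 0.12. IFI27 was lower with a log2 difference of -7.16 ± 0.27, CALCR with -5.49 ± 0.18, the chromatin organiser SATB1 with -4.49 ± 0.13 and TFF3 with -4.31 ± 0.09. The parental level of TWIST1 (4.70) and the ex-resistant levels of IFI27 (4.62) and CALCR (4.07) lie close to the floor. CCND1 was lower than in parental cells by a difference of -0.99 ± 0.20 and CDKN1A by -0.68 ± 0.08, and CDK6 was higher by 0.78 ± 0.11 (adjusted p = 0.000179). The levels of CDK6, 4.02 in parental and 4.81 in ex-resistant cells, both lie close to the floor. TGFBR3 stood at -3.20 ± 0.13 and TFF1 at -3.52 ± 0.26, while SMAD4 (-0.08 ± 0.08, adjusted p = 0.471) did not pass.

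G2/M and mitosis had 29 of 39 lower and 1 higher (32 and 1 adjusted over the list alone), with CENPF at -0.80 ± 0.07, the kinetochore gene NDC80 at -0.98 ± 0.09, NUSAP1 at -0.75 ± 0.08 and MKI67 at -0.80 ± 0.13, and the list passed (median -0.54, adjusted p = 1.45e-09, adjusted p = 0.509 with an estimated correlation). E2F targets had 24 of 43 lower and 3 higher (25 and 5 adjusted over the list alone), with GINS1 at -0.95 ± 0.09 and CCNE1 at -1.19 ± 0.12, and passed as well (median -0.29, adjusted p = 0.000466, adjusted p = 0.665 with an estimated correlation). Both probe sets were lower in 6 and opposite in 2 of the 12 G2/M genes with 2 bright probe sets, and lower in 3 and opposite in 4 of 13 E2F targets. The CDK4/6-RB axis had 8 of 27 higher and 12 lower (9 and 12 adjusted over the list alone, adjusted p = 0.478). CCND3 was at -0.58 ± 0.11, and E2F1 (-0.13) and CDKN2B (0.02) did not pass. RB1, on chromosome 13, was at -1.01 ± 0.12 and CCNE2 at -0.83 ± 0.11 by the brightest probe sets, and at 0.85 and 1.46 by the other. CDK4 at 0.30 ± 0.11 lost its call without any 1 array other than parental replicate 1 or 2, in 7 of 9 fits (0.16 to 0.32, adjusted p = 0.0510 to 0.139), and CDK2 at 0.21 ± 0.07 lost it without parental replicate 1 or 3 or ex-resistant replicate 1 or 2 (0.17 to 0.22, adjusted p = 0.0563 to 0.114). Both calls were also lost in the fit to 6 arrays and after median centring (0.26 to 0.30, adjusted p = 0.0668 to 0.0758, and 0.17 to 0.21, adjusted p = 0.0529 to 0.0862). Histone genes had 7 of 10 higher, with H4C8 at 1.67 ± 0.12 and H2BC9 at 1.08 ± 0.09, and 3 lower, and did not pass (adjusted p = 0.0686).

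The list with the lowest p was the oestrogen response with an estimated correlation or by fry, and the interferon-stimulated genes at the preset correlation. Of 35, 31 were lower and 0 higher, over all genes and adjusted over the list alone, with IFIT1 at -4.59 ± 0.20, MX1 at -3.34 ± 0.16 and IFIT5 at -2.75 ± 0.14, a median of -1.19 and adjusted p = 1.73e-16 (adjusted p = 0.191 with an estimated correlation). Oestrogen-responsive genes had 18 of 35 lower and 6 higher (20 and 6 adjusted over the list alone), with the hormone gene STC2 at -2.07 ± 0.10 and IGFBP5 at -1.77 ± 0.11, and passed (median -0.40, adjusted p = 0.00201, adjusted p = 0.156 with an estimated correlation). Both probe sets were lower in 8 of 14 such members and opposite in 0. ESR1 was at -0.43 ± 0.07 by its brightest probe set and at 0.87 by another, PGR at 0.36 ± 0.12, a call lost without parental replicate 1 or 2 or ex-resistant replicate 1 or 2 (0.23 to 0.38, adjusted p = 0.0595 to 0.143) or after median centring (0.32, adjusted p = 0.0569), and GREB1 (-0.21) did not pass. GREB1 passed without resistant replicate 3 (-0.21, adjusted p = 0.0411) and under 2 alternatives that kept every array (-0.44 to -0.21, adjusted p = 0.0364 to 0.0425). Senescence-associated secretory genes had 15 of 29 lower and 4 higher, with equal counts adjusted over the list alone, with SERPINE2 at -2.88 ± 0.12, TIMP1 at -2.63 ± 0.20 and CXCL2 at -1.48 ± 0.10 (median -0.48, adjusted p = 0.0106, adjusted p = 0.172 with an estimated correlation). Antigen presentation had 7 of 18 lower, with PSMB10 at -0.57 ± 0.07, and 2 higher (adjusted p = 0.421).

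TGF-beta ligands, receptors and SMADs had 7 of 32 higher and 8 lower, with equal counts adjusted over the list alone (adjusted p = 0.912). TGFBR1 was higher by 0.69 ± 0.12 and the BMP receptor gene BMPR1B by 0.80 ± 0.10. SMAD2 was at -0.83 ± 0.12 and SMAD3 at -0.68 ± 0.12 by the brightest probe sets, and at 0.37 and 0.44 by another, and TGFBR2 (0.02) and SMAD7 (-0.17) did not pass. TGF-beta target genes had 9 of 33 higher, with ID1 at 1.38 ± 0.15, and 7 lower, with PMEPA1 at -2.02 ± 0.15 and fibronectin gene FN1 at -1.16 ± 0.10, again equal over the list alone (adjusted p = 0.821).

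Other lists did not pass, and adjusted over the list alone the counts of lists that did not pass differed by at most 2 genes. Luminal genes had 11 of 30 higher, with CLDN3 at 1.36 ± 0.09, CLDN4 at 1.09 ± 0.09 and KRT7 at 1.18 ± 0.10, and 9 lower (adjusted p = 0.478). Mesenchymal genes had 7 of 29 higher, with VIM at 1.14 ± 0.13, and 4 lower (adjusted p = 0.5). Basal markers had 1 of 17 higher and 4 lower, with MYLK at -0.58 ± 0.12 (adjusted p = 0.478). Fibroblast markers had 4 of 16 higher and 2 lower (adjusted p = 0.523), and leukocyte markers had 4 of 18 higher and 1 lower, CD74 at -0.71 ± 0.12 (adjusted p = 0.478). Cholesterol synthesis had 8 of 18 higher, with TM7SF2 at 1.17 ± 0.08 and SC5D at 0.97 ± 0.09, and 4 lower (adjusted p = 0.523). Fatty acid synthesis had 3 of 15 higher and 2 lower (adjusted p = 0.936). The ATF4 list had 9 of 30 higher, with PSAT1 at 2.90 ± 0.13, ASNS at 1.35 ± 0.07 and DDIT4 at 0.82 ± 0.08, and 6 lower (adjusted p = 0.461). Hypoxia and glycolysis had 5 of 35 higher and 13 lower, with P4HA2 at -0.87 ± 0.07 (adjusted p = 0.174). Oxidative phosphorylation had 8 of 38 higher, with UQCRC1 at 0.96 ± 0.09, and 5 lower (adjusted p = 0.535), and p53 targets had 6 of 23 higher, with TP53I3 at 1.68 ± 0.10, and 11 lower, with PLK2 at -1.80 ± 0.14 (adjusted p = 0.314). Exosome genes had 8 of 27 higher, with RAB27B at 1.26 ± 0.11, and 10 lower, with CD63 at -0.82 ± 0.07 (adjusted p = 0.523). MicroRNA processing had 3 of 11 higher and 1 lower (adjusted p = 0.912). Lysosome genes had 9 of 34 higher and 11 lower, with the protease gene CTSD at -1.16 ± 0.10 (adjusted p = 0.5). MAPK output had 5 of 22 higher and 8 lower, with PHLDA1 at -2.86 ± 0.08 (adjusted p = 0.523). Receptor tyrosine kinases had 6 of 30 higher and 7 lower, with FGFR3 at -1.56 ± 0.09 and ERBB4 at -1.26 ± 0.09 (adjusted p = 0.821). FGFR1 did not pass (0.00) by its brightest probe set and was at 0.76 by another. Drug transport had 4 of 26 higher, with ABCC5 at 0.71 ± 0.08, and 7 lower (adjusted p = 0.936). Of the 4 genes of 14q32, 1 was higher and 1 lower.

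In this comparison 5358 genes were called, 2528 higher and 2830 lower, and 486 differed at least 2-fold (184 and 302). The arrays of the 2 groups did not overlap in 53.5% of genes, against 10% by chance. Among the 2408 genes with 2 bright probe sets, the brightest called 1326 and both alike 627, 43 of them with at least a 2-fold difference, and the lowest adjusted p of a list with an estimated correlation was 0.156. The moderated F-test over the 3 groups called 6228 genes. A list's median and mean differed in sign in several lists that did not pass, such as the TGF-beta ligands, receptors and SMADs in resistant against parental cells (median 0.04, mean -0.07, tested as lower) and TGF-beta targets in ex-resistant against parental cells (median 0.10, mean -0.04, tested as higher). For the CDK4/6-RB axis in ex-resistant against resistant cells the median was 0.04 and the mean -0.13. In the lists that passed, median, mean and test had 1 sign.

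**Figure D3:**
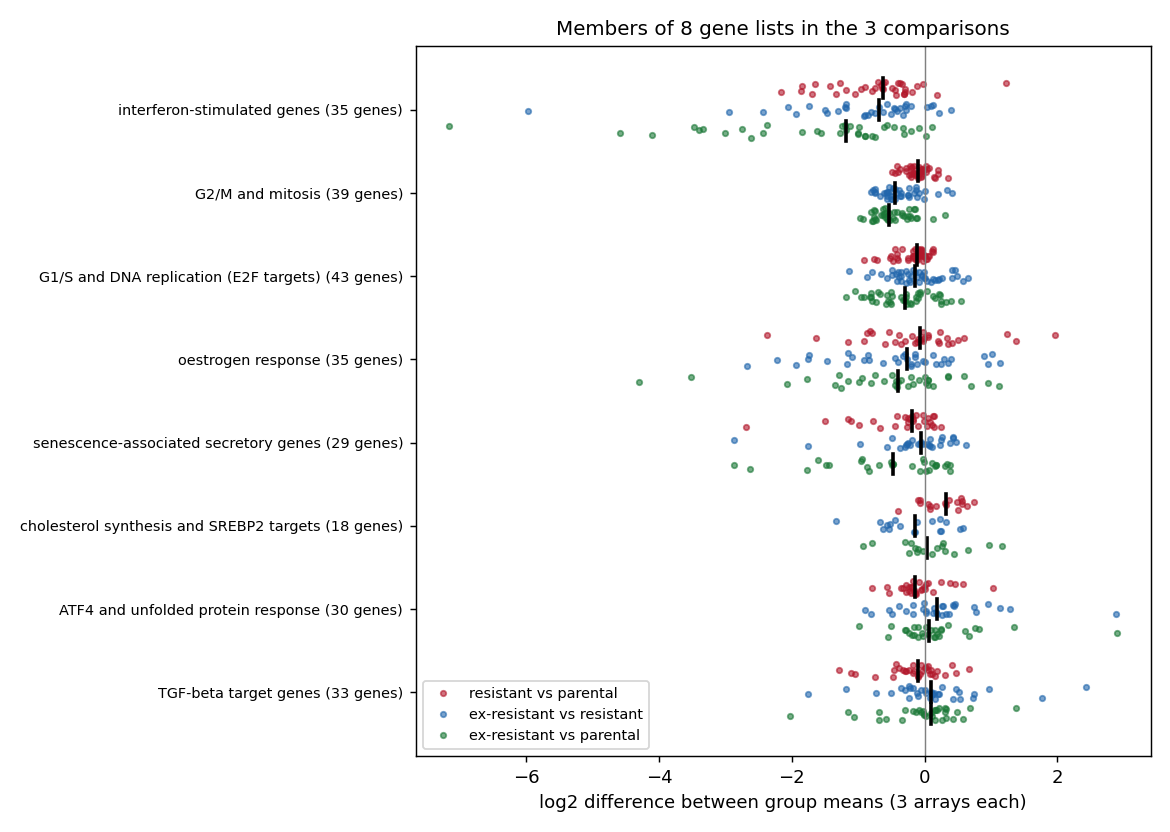
Log2 differences of the measured members of 8 gene lists in the 3 comparisons (3 arrays per group), with 1 point per gene and the median as a black bar. The interferon-stimulated genes had medians of -0.63, -0.69 and -1.19, and the G2/M genes had a median of -0.44 in ex-resistant vs resistant and -0.54 in ex-resistant vs parental cells.

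The 3 groups together addressed which changes of resistant cells were undone after drug removal. Dystrophin gene DMD, the nuclear receptor gene NR2F1, the lipoprotein receptor gene OLR1 and the claudin gene CLDN1 fell by 4.37 ± 0.18, 3.89 ± 0.13, 3.66 ± 0.14 and 3.61 ± 0.10 in resistant cells and rose by 2.20 ± 0.18, 1.61 ± 0.13, 3.00 ± 0.14 and 1.18 ± 0.10 in ex-resistant against resistant cells (SE, n = 3 arrays per group). All 4 were still lower than in parental cells, with differences of -2.17, -2.29, -0.66 and -2.42. SULF1 fell by 3.37 ± 0.17, rose by 3.52 ± 0.17 and was not called against parental cells by its brightest probe set (0.16, adjusted p = 0.477), but was with the mean of its probe sets (0.33, adjusted p = 0.0361). SMAD4, ACTA2, BAMBI and CYP1A1 also returned to a level that was not called against parental cells. The iron oxidase gene HEPH and the membrane transporter gene XK rose by 3.20 ± 0.08 and 2.14 ± 0.10 and then fell by 1.47 ± 0.08 and 1.05 ± 0.10, to remain higher than in parental cells by 1.72 and 1.09. Of the 6 largest rises that were followed by a fall, 5 remained higher, with HEY2 at 2.37, TRIM58 at 0.95 and MTSS1 at 0.29 (0.19, adjusted p = 0.0611, with the mean of its probe sets). The fall of HEY2 was small (-0.38 ± 0.12), and its call depended on single arrays, as given below. VCX2 rose by 2.85 ± 0.11, fell by 3.02 ± 0.11 and was not called against parental cells (-0.16, adjusted p = 0.228; -0.28, adjusted p = 0.0368, without parental replicate 3). TWIST1 and CALCR were changed in the same direction in ex-resistant and resistant cells, as were TGFBR3, TFF1, TFF3 and SATB1.

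Of the 2319 genes changed in resistant cells, 921 (39.7%) moved in the opposite direction in ex-resistant cells. Of the 921, 574 were not called against parental cells. A further 206, such as CCND1, were called beyond the parental level, and 141 were still called in their first direction. The opposite move held for 607 of the 1209 genes that had risen (50.2%) and 314 of the 1110 that had fallen (28.3%). In ex-resistant against parental cells, 1353 genes (58.3%) were called in the same direction as in resistant cells. These include the 141, so the 2 shares overlap. Independent calls would give 469.8 genes in the opposite and 518.1 in the same direction. For the moves in the opposite direction they would give 23.49% of the risen and 16.74% of the fallen. The comparisons share arrays. Their covariance was -0.0274 for the reversal pair, against -0.00508 in simulations without group differences, and 0.0805 for the pair against parental cells, against 0.00508. The correlations were -0.1951, against -0.5 (-0.5198 to -0.4832) in the simulations, and 0.5051, against 0.5002 (0.4849 to 0.5173). In 6 ways of dividing the arrays so that the 2 differences shared none, a check added after the data had been seen, the covariances were -0.0305 to -0.0113 (r of -0.205 to -0.0718) and 0.0680 to 0.0862 (r of 0.400 to 0.498). The differences still shared a group, resistant cells in the first pair and parental cells in the second. A deviation of that whole group would give the same signs, so neither check can tell it from changes undone or kept. With both bright probe sets required, among the same 2408 genes, 81 of 306 changed genes (26.5%) moved back, 59 of them not called against parental cells, and 121 (39.5%) were called in the same direction.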

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

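The tests in this part, and what the counts over other splits of the arrays were expected to show, were set down after the results they measure had been seen, and the way of naming groups in the splits for the reversal was changed once after a first version.

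Probe sets that carry no single gene symbol, 3151 in all, were not used in the comparisons of genes, and they held signal too. Of these, 282 were called in resistant against parental, 1092 in ex-resistant against resistant and 1174 in ex-resistant against parental cells.

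The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In fits to these 6 arrays, the real split of resistant and parental arrays called 2315 genes and 218 with at least a 2-fold difference, 1 of the 10 splits reached these counts, and the highest other gave 0 and 0. For ex-resistant and resistant arrays the real split gave 4660 and 399, and for ex-resistant and parental arrays 5051 and 486, each reached by 1 split, with 0 and 0 as the highest other. Gene lists past the threshold numbered 5 in each comparison. The highest other split gave 5, 3 and 4, so that 2, 1 and 1 splits were as large. Repeat numbers may pair parental with resistant arrays. The real split of these was therefore also set beside the 4 splits that part all 3 such pairs. Among them the highest other gave 0 genes and 5 lists, and the remaining splits keep 2 arrays of some pair on 1 side.

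For the F-test, 100 of the 280 splits of the 9 arrays into 3 groups of 3 were drawn. Only the real one reached its 6228 genes, 1 of 100, and the highest other, which kept the ex-resistant arrays in 1 group, gave 3338. Many other splits gave 0 genes, since a split that mixes the groups widens the spread within them. The draw thus shows only that the arrays cluster by their real groups. The draw cannot separate a change of the cells from a difference between cultures or batches, since separate cultures are not stated. It also left aside that repeat numbers may pair parental with resistant arrays. For the reversal, 100 of the 1680 ways of naming 3 groups of 3 were drawn. Here 1 of 100, the real one, reached 921 genes, with 447 as the highest other. Of the 99 others 94 called 0 genes in the first comparison, so that no reversal could be counted, and this draw decides nothing about the reversal. A first version took for each drawn split the largest reversal over its 6 namings, and then 4 of 100 splits were as large, with 2688 genes as the highest other. The 3 other splits among these kept the ex-resistant arrays in 1 group, which points to the distance of these arrays from the rest.

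Probe sets of the same gene moved less alike where the ex-resistant arrays entered. A further normalization cannot decide on scaling of whole arrays, since RMA had already quantile normalized the values and little was left to change. After quantile or cyclic loess normalization r between the probe sets was at most 0.418 in ex-resistant against resistant cells, where it was 0.421 as deposited. Both lie below the 0.824 to 0.876 of resistant against parental cells. Probe sets that match several transcripts are argued against as the whole cause, since r was 0.558 (0.377 to 0.696) among genes whose probe sets match 1 transcript each, against 0.887 (0.808 to 0.931). Such probe sets were taken by the plain _at ending of their names, without a mapping to transcripts. In ex-resistant against resistant cells 3.33% of probe sets with that ending differed at least 2-fold, 7.94% with _s_at and 5.42% with _x_at. In resistant against parental cells these shares were 1.66%, 1.64% and 0.87%. A handling difference that varies from array to array may contribute: the gap between probe sets that set 1 ex-resistant array apart correlated with the gap between the other ex-resistant arrays with r of 0.481 (0.448 to 0.513) and 0.444, but 0.046 for replicate 3, against -0.022 to 0.303 within the other groups. A change of transcript forms in ex-resistant cells stays open as an untested biological explanation, and since all 3 arrays of the group share it, the design confounds it with handling.

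Interferon-stimulated genes were lower in resistant and lower again in ex-resistant arrays. Shifts of probe sets without regard to gene function are argued against, since the lowest median of 10000 random lists of the same level was -0.31 in ex-resistant against resistant cells, where the list stood at -0.69. Random lists lack the correlation between the members, estimated at 0.278. With an estimated correlation camera did not pass the list there (adjusted p = 0.512) or in resistant against parental cells (adjusted p = 0.169). Handling of the ex-resistant arrays as the whole cause is argued against by the median of -0.63 in resistant against parental cells, where no ex-resistant array enters and random lists reached -0.15. That comparison cannot bear on the second fall, in ex-resistant against resistant cells, which the design confounds with handling of the ex-resistant arrays. A lower dose of the members that lie on chromosome 21, such as MX1, is argued against as the whole cause. The median was -1.19 in ex-resistant against parental cells over the 33 members on other chromosomes. That median cannot exclude an effect of a lower dose of chromosome 21 on members elsewhere, which was not tested and stays open. Medians over 91 genes of chromosome 21 were -0.19 in resistant against parental, -0.33 in ex-resistant against resistant and -0.527 in ex-resistant against parental cells. A lower interferon response of the cells may explain the pattern, as a hypothesis found and tested on the same data, and with these arrays it stays open what lowered it.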

How the results depend on the processing

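Where every array was kept, the counts of called genes, the F-test and the reversal counts stayed within 1.5-fold of the reported ones under the replicate block, the fit to 6 arrays (counts of called genes alone), quantile normalization, median centring, cyclic loess, the filter at a mean of 5, the mean of a gene's probe sets, another moderation and array weights. The replicate block changed no call of a list other than the oestrogen response (adjusted p = 0.0806) and fatty acid synthesis (adjusted p = 0.0505) in resistant against parental cells. Fry, which does not compare a list with other genes, passed 13, 16 and 20 of 27 lists in the order of the report, with 6, 4 and 5 of the 8, 4 and 5 that camera passed. No list that passed had a median of another sign after quantile normalization, median centring or cyclic loess. Without genes under the median level, 2-fold counts were 96, 215 and 268 in the order of the report, among 5983 genes. With the probe set of largest interquartile range, 2-fold counts were 837 for ex-resistant against resistant and 905 against parental cells, and the cause was not tested. With each of the 19064 probe sets of 1 symbol tested as itself, these comparisons called 8009 and 8615 probe sets (1001 and 1093 at least 2-fold) and the F-test 9823. These counts have a larger base than the 11963 genes of the main fit. Why the 2-fold counts rose by more than that base was not tested. At a threshold of 0.01, resistant against parental called 1343 and ex-resistant against resistant 3199 genes, and the reversal counts were 499, 361 of them not called against parental cells, and 739 in the same direction. Requiring both of 2 bright probe sets, added after the data had been seen, gave 306, 557 and 627 genes (22, 44 and 43 at least 2-fold) and reversal counts of 81, 59 and 121, among 2408 genes of which the brightest probe set alone called 553, 1264 and 1326.

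Leaving out 1 array at a time gave 1668 to 2398 genes (216 to 230 at least 2-fold) for resistant against parental, 4036 to 4887 (371 to 441) for ex-resistant against resistant and 4530 to 5364 (460 to 536) for ex-resistant against parental cells, 5367 to 6130 for the F-test, and 688 to 909, 430 to 589 and 983 to 1339 for the reversal counts. Of 257 values of named genes, 11 lost their call without some array, 8 gained one and 0 changed direction. Beside those given with the comparisons, the losses were TWIST1 (0.36 to 0.41, adjusted p = 0.0551 to 0.0674) and HEY2 (-0.36 to -0.25, adjusted p = 0.0588 to 0.0750) in ex-resistant against resistant cells, and the gain was CALCR without resistant replicate 1 in the same comparison (-0.44, adjusted p = 0.0495).

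Among named genes, directions turned under the alternatives in how probe sets stand for a gene and under no other that was run, and the cause was not tested. With the mean of all probe sets, CCNE2 was at 0.84 in ex-resistant against resistant and 0.32 against parental cells, RB1 at 0.22 in the first, and ESR1 at 0.13 and 0.17. With the probe set of largest interquartile range, CCNE2 was at 2.04 and 1.46, RB1 at 0.92 and 0.85, ESR1 at 0.85 and 0.87, and FGFR1 at 0.76 in ex-resistant against resistant cells. The mean also ended the calls of CDK2 (-0.23), TRIM29 and EGFR in resistant against parental, SMAD2 (-0.11) in ex-resistant against resistant, and RB1 (-0.08), SMAD3 (-0.09) and MTSS1 in ex-resistant against parental cells. The largest interquartile range ended those of RB1 (-0.07), RRM2 (-0.24), SQLE (0.37) and ELOVL2 in resistant against parental cells. E2F1 gained a call in ex-resistant against resistant cells with both and with array weights (-0.31 to -0.19, adjusted p = 0.0319 to 0.0480) and against parental cells with both (-0.32 to -0.22, adjusted p = 0.0246 to 0.0436). Cyclic loess ended the call of MKI67 in ex-resistant against resistant cells (-0.34, adjusted p = 0.0555), and a threshold of 0.01 ended 13 of the 257. The alternative for linear values was not run, since the values were log2. Of the 257 values, 38 compared a group with a mean under 5, close to the background of the arrays, and 30 of these were called, such as TWIST1, CALCR, IFI27, DMD, HEPH and SERPINE2. Background limits what can be seen of a change there, and the size of such a difference depends on it.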

Other observations

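The gene families and the tests on chromosomes in this part were all chosen after the values had been seen.

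Metallothioneins, small proteins that bind zinc and copper, were higher in ex-resistant than in resistant cells. All 8 measured genes were called higher, such as MT1F (1.14 ± 0.27, SE, n = 3 arrays per group), MT1X (1.06 ± 0.31), MT1M (0.85 ± 0.13, at levels of 3.44 and 4.29 close to background) and MT2A (0.68 ± 0.23), with a median of 0.84, and 7 of them after median centring. Of 18 families defined by symbol, this one passed in that comparison (adjusted p = 0.0121, adjusted p = 0.584 with an estimated correlation), and against parental cells 5 were higher and it did not pass (adjusted p = 0.0673). The sequences of these genes are alike, and how far their probe sets share transcripts was not tested. Protocadherins, a family of neuronal adhesion genes, had 10 of 27 higher and 1 lower in ex-resistant against resistant cells (adjusted p = 0.0206, adjusted p = 0.584 with an estimated correlation) and 13 higher and 0 lower against parental cells (median 0.25, adjusted p = 0.00884, adjusted p = 0.722 with an estimated correlation), with PCDHB6 at 0.89 ± 0.07 and PCDHB12 at 0.87 ± 0.10. Of these 13, 7 had a group mean under 5, close to background, and against parental cells the counts were 10 and 1 after quantile normalization (median 0.20) and 11 and 2 after cyclic loess (median 0.18). Claudins, which seal epithelial junctions, passed in ex-resistant against resistant cells, with 7 of 16 higher and 2 lower (adjusted p = 0.0353, adjusted p = 0.584 with an estimated correlation), and did not pass against parental cells, with 9 higher and 2 lower (adjusted p = 0.366).

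In resistant against parental cells, proteasome subunit genes were lower, 9 of 34 with 0 higher (median -0.14, adjusted p = 0.000638, adjusted p = 0.387 with an estimated correlation). The calcium-binding S100A genes were lower too, 6 of 14 with 1 higher (median -0.30, adjusted p = 0.00911, adjusted p = 0.387 with an estimated correlation).

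Among 7442 genes with a mean over 6 and a known position, those of chromosome 13 were lower in resistant and ex-resistant arrays. Shifts without regard to position are argued against, since 1.22% of 10000 draws that slid the log2 differences along the gene order gave any chromosome a median as low. Handling of the ex-resistant arrays as the whole cause is argued against by the median of -0.297 over 113 genes in resistant against parental cells, where no ex-resistant array enters. That comparison cannot bear on the part of the difference that came with the ex-resistant arrays. A lower dose of the whole chromosome is a candidate explanation, since both ends were lower in resistant cells, by medians of -0.285 (-0.343 to -0.207) and -0.31 (-0.363 to -0.233). DNA copy number was not analysed here, so the hypothesis, found and tested on the same data, stays open, and other chromosomes moved both ways in resistant against parental cells, with medians such as -0.19 for 21, -0.14 for 4, -0.085 for 18, 0.165 for 6, 0.13 for X and 0.118 for 7. In ex-resistant against parental cells the median of chromosome 13 was -0.373 (69 of 113 genes lower, 8 higher). That of chromosome 21 was lower still, at -0.527 (67 of 91 lower, 4 higher). Against resistant cells the medians were -0.077 for 13 and -0.33 for 21.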
